A study of Arabidopsis thaliana with 70 samples.

How the data were processed

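The series holds PCR-free genomic DNA libraries of 67 epiRILs (F9), 2 Col-0 samples and 1 met1-3 sample, each made, per the labels, from about 10 seedlings (100 mg) grown for 14 days with 16 h of light, with inserts of 350 bp. No sample was left out. Per the submitters' processing notes, reads were trimmed with Trimmomatic, aligned with Bowtie2 to TAIR10, handled with bedtools 2.26.0 and called with MACS2. Per the file headers, MACS 2.1.0.20151222 was run once per library with Col-0 replicate 1 as the control, without a model, with fragments extended to 400 bp, a tag size of 75 bp, at most 1 tag kept per position and strand, the larger dataset scaled to the smaller, local backgrounds over 1000 and 10000 bp, and a q cutoff of 0.05. The control library was thus also called against itself and its deposited list is empty. The deposited pileup is a signal, the coverage by extended fragments at the summit, which reaches 800 at most. The deposited p and q values are given as -log10 p and -log10 q of the Poisson test of MACS. The deposited fold enrichment is the authors' ratio of the pileup to the local control level, and is used here to describe regions. The genome size in the headers equals the summed length of the 5 nuclear chromosomes of the reference, so nuclear coordinates were used as TAIR10. The annotation of the organelle chromosomes was not used.

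Peaks of all libraries were merged where they overlapped by at least 1 bp, and a library was taken to have a region if it had a peak in it. Depth per library was read as total and kept tags from the headers: 8.25 to 46.3 M tags per epiRIL, 59.6 and 53.9 M for Col-0 and 5.72 M for met1-3, of which 23.2 to 44.1% were removed as duplicates in the epiRILs. The peaks hold no counts of molecules, so intervals are given only for shares of lines and, in the last part, of private regions (exact Clopper-Pearson, 95%). For a count of 0 the limit is what 3 counts of the total allow. The reference names 37899 nuclear gene models and does not mark transposons as such. The 3901 pseudogenes with an mRNA and the product "uncharacterized protein" were taken as transposable element genes, since all 17 transposon genes of the lists fixed in advance are of this kind, and 3950 models resulted with those described as transposases or the like. Classes came from keywords in the descriptions and the fixed lists, giving 11 CACTA, 16 Mutator, 12 hAT, 18 Copia, 1 Gypsy and 15 LINE models, so most elements have no class. Helitrons had none and were not tested.

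Per-library counts, covered length and share of peaks over elements were compared between groups by exact permutation tests over all ways to choose the Col-0 or met1-3 libraries. Regions were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 618 regions and a threshold of 0.05. Classes were tested against 1000 random placements of the regions within their chromosomes and adjusted over 6 classes, as were the Fisher tests by class. Sharing with met1-3 was tested with 10000 permutations over regions, and correlations with 100000 resamples, with seed 1. Pericentromeric windows were fixed as 12 to 18 Mb on chromosome 1, 1 to 7.5 Mb on chromosome 2, 10 to 17 Mb on chromosome 3, 1.5 to 7 Mb on chromosome 4 and 9 to 16 Mb on chromosome 5. Ribosomal DNA windows were the first 0.02 Mb of chromosomes 2 and 4 and 14 to 14.3 Mb on chromosome 3.

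Regions named in the text follow a rule fixed in advance. It took the 15 regions called in most lines and in neither Col-0 library, with ties broken by median fold. It also took the 10 with the highest median fold among those called in at least 4 lines and no Col-0 library, every element of the fixed lists, up to 5 CACTA regions, and the region over genes only that most lines called. Names come from the gene or element a region overlaps most; EVD, ATR, CACTA1 and VANDAL21 Hi are named by the fixed lists. AT1G35280, AT4G07526, AT4G08750, the private stretches and their genes were chosen after their values were seen.

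Alternatives were a fold of at least 2, a -log10 q of at least 10, the removal of organelle chromosomes, ribosomal DNA and the insertion, each Col-0 library left out, medians, 50% cover by elements, gaps of up to 1000 bp, 50% cover of a region by a peak, and regions of Col-0 left out. Chosen after seeing the data were classes by tblastx similarity (E-value limit 1e-10) to the named elements, which gave 195 CACTA-like, 323 Mutator-like and 434 Copia-like models, with 13 of 14 models that had both a description and a similarity given the same class, classes without the elements of the fixed lists, runs without epi34, epi12 or epi69, and the nuclear counts and classes by line without Col-0 replicate 1. Shared sequence between elements was measured with blastn at 90% identity or more, other copies of private regions in the reference with blastn at the same identity over at least 75 bp, and CACTA-type ends as an 8 bp terminal motif within 150 bp of both edges of a region. On simulated lists, 600 of 600 regions were recovered, 60 of 60 regions set in every line passed and no others did. The other regions lay apart and were called at random in lines and Col-0 alike, and no simulated library was its own control. This checks the code and does not measure false calls in the real lists. In 400 random sets the placement test gave p under 0.05 in 23, and 100 of 200 regions set on elements gave p = 0.001. The regions of the random sets were placed independently, so this does not cover the neighbouring pieces of the real lists. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and Biopython 1.88, and BLAST+ 2.17.0. Raw reads and split reads at insertion sites were not used here.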

Results

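Genomic DNA of 70 Arabidopsis thaliana samples was sequenced from libraries made without PCR: 67 epigenetic recombinant inbred lines (epiRILs), 2 wild-type Col-0 samples and 1 sample of met1-3, a mutant of the CG methyltransferase MET1. The epiRILs descend from met1-3 and were at generation F9, and each was 1 library of 10 seedlings. The question behind the design, per the title of the series, is whether CACTA transposons and elements related to them became mobile in these lines. The measurement is a list of peaks per library, each a stretch with more reads than the library of Col-0 replicate 1, which served as the control of every list. All coordinates are on TAIR10. MACS kept 11.3 ± 4.55 M tags per epiRIL (SD, n = 67), from 6.04 M in epi36 to 28.5 M in epi54. It kept 37.3 and 34.9 M in the Col-0 libraries and 4.18 M in met1-3, so depth differed between the groups. The 69 lists that held peaks gave 15949 peaks, which merged into 618 regions, 583 of them called in at least 1 epiRIL. The labels do not say whether the samples were grown separately, so the p-values measure only the spread between these samples.

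Most peaks of the epiRILs lay over organelle DNA and its nuclear copies. The mitochondrial chromosome held 5239 of the 15949 peaks (32.8%). A further 4917 peaks (30.8%) lay in the large mitochondrial insertion of chromosome 2 between 3.2 and 3.6 Mb. The plastid chromosome was called as a single peak of at least 154 kb in all 67 lines and in met1-3, and in neither Col-0 library. The windows around the 45S ribosomal RNA genes held 612 peaks (3.84%), and 5113 peaks (32.1%) lay elsewhere on the nuclear chromosomes. The epiRILs had 233 ± 74.7 peaks per library (SD, n = 67), from 113 to 468. Col-0 replicate 1 had 0 peaks, because it was called against itself, and replicate 2 had 42. The means differed by 212 peaks (exact permutation test, two-sided, p = 4.26e-04, the smallest that 67 lines against 2 libraries can give). The 0 of replicate 1 was fixed by that call, and against replicate 2 alone the difference was 191 peaks (exact permutation p = 0.0294). The covered length was 803 ± 174 kb (SD, n = 67) against a Col-0 mean of 10.5 kb, a difference of 792 kb (exact permutation p = 4.26e-04), and of 781 kb against replicate 2 alone (exact permutation p = 0.0294). The part of the genome outside the organelle chromosomes, the insertion and the ribosomal RNA windows still holds nuclear sequence like that of organelles. An example is the region of AT3G20362, called in 66 lines and like an organelle over 100% of its sequence. Where organelle DNA is left out, here and below, the organelle chromosomes are meant. In this part the lines had 74.8 ± 26.3 peaks (SD, n = 67), from 36 to 258. Col-0 replicate 2 had 41, inside their range. The difference was 54.3 against both Col-0 libraries (exact permutation p = 0.0303) but 33.8 against replicate 2 alone (exact permutation p = 0.0735), so it did not hold up without the fixed 0. The covered length there differed by 118 kb against both (exact permutation p = 0.0294) and by 108 kb against replicate 2 alone (exact permutation p = 0.0441). This length includes regions called in nearly every line and not in replicate 2, such as that of AT2G08986, called in all 67 lines. Across such nuclear regions below the highest pileup, ribosomal ones included, fold rose with the ratio of kept tags, control over line (median Spearman rho 0.961). How much of the difference in length they make up was not tested, so it does not show an excess apart from depth. Line epi12 stood apart in mitochondrial DNA and its insertion, where peaks covered 0.417 and 6.04 kb, against means of 286 and 204 kb over the lines. It had 1 mitochondrial peak and 10 in the insertion, against means of 76.6 and 71.9. A low count can also mean few long peaks, as in epi59, with 11 in the insertion over 265 kb.

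**Figure D1:**
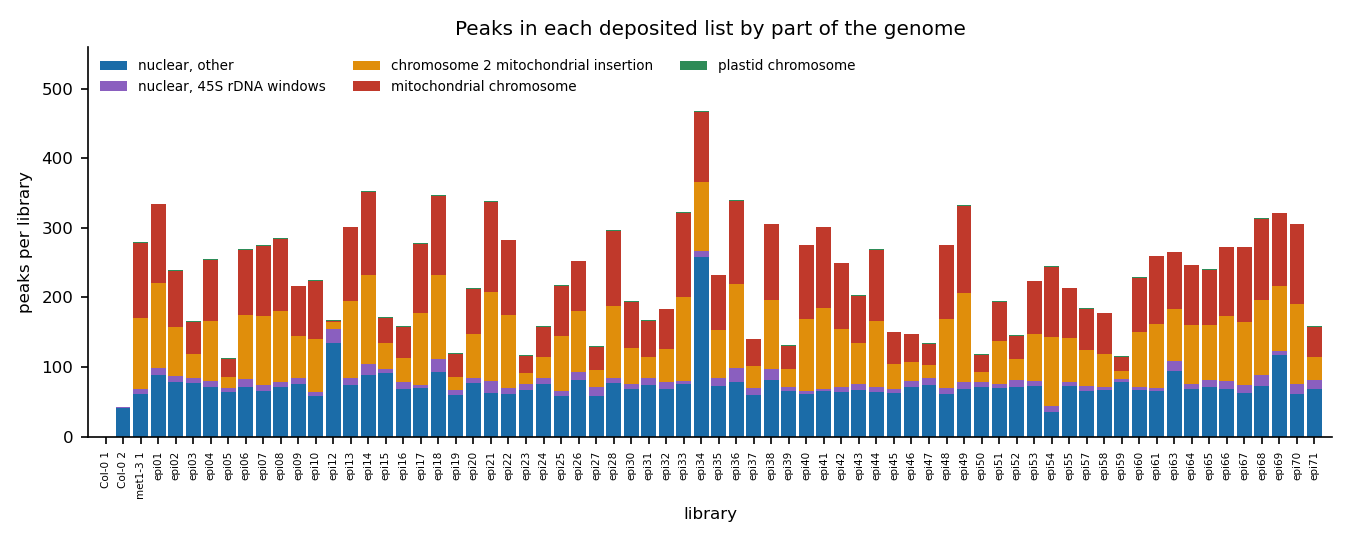
Peaks in each deposited list (vertical axis, number of peaks) for the 70 libraries (horizontal axis), stacked by part of the genome. Col-0 replicate 1 has 0 peaks and replicate 2 has 42, the lines have between 113 and 468, and epi34 is highest with 258 peaks in the nuclear part outside the windows.

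The regions called in all 67 lines lay over ribosomal DNA, organelle DNA and its insertion, the edges of transposable element genes, uncharacterized genes and unannotated blocks. They included the 45S ribosomal DNA of chromosome 3 (chr3:14191557–14205347, named by AT3G06365, the annotated RNA it overlaps most) with a median fold of 3.67, and that of chromosome 2 (chr2:917–10483, AT2G01008) with 3.67. Fold here and below is the authors' own enrichment of each peak over Col-0 replicate 1; at ribosomal and plastid DNA it was close to the ratio of kept tags between control and line, with a median of 0.997 times that ratio at the regions that reach the highest pileup. On chromosome 4, regions at the edges of the transposable element genes AT4G06700 (chr4:3950263–3956189) and AT4G06477 (chr4:3054246–3061435, named by AT4G05185) had median folds of 3.59 and 3.44, and on chromosome 5 a region at the edge of AT5G29550 (chr5:11184446–11188926) had 3.59. The element genes lay under 5.74, 6.41 and 1.54% of these regions, and 66, 67 and 3 lines had a peak over the gene itself. Also on chromosome 5, 3 unannotated blocks between positions 11725933 and 11736454 had 3.08 to 3.38. On chromosome 3, regions without annotation at 13588578–13592903 and 13705300–13708075 had 3.67 and 2.74. The genes AT2G08986 (chr2:3615575–3627888, 3.54), AT2G16586 (chr2:7190625–7191571, 3.12) and AT1G40104 (chr1:15081814–15086130, 2.77), which code for uncharacterized proteins, were also called in every line. So was the block of the mitochondrial insertion around AT2G07806 (chr2:3483128–3509711), with a median fold of 2.37. Among all regions, 58 of 618 were called more often in epiRILs than in Col-0 (Fisher's exact test, two-sided, smallest adjusted p = 0.0115). In this direction 72 had an unadjusted p under 0.05. Both counts rest in part on the lack of peaks in Col-0 replicate 1, which was fixed by its call against itself. In the other direction 35 regions, called in Col-0 replicate 2 and in no line, had an unadjusted p under 0.05 and none passed. No region could be called in both Col-0 libraries, since replicate 1 was called against itself, so this lack of regions is no result. The 58 were called in 64 or more lines each, and 37 lay in nuclear DNA outside the windows, 9 in the mitochondrial chromosome, 7 in the insertion, 4 in ribosomal DNA and 1 in the plastid chromosome. The count was 0 without Col-0 replicate 1, 0 without Col-0 replicate 2 and 0 for peaks with a fold of at least 2 (Fisher's exact test, 56, 57 and 24 regions called more often at an unadjusted p under 0.05). It was 35 without organelle DNA, ribosomal DNA and the insertion, 31 with regions merged across gaps of 1000 bp, and 32 where a peak had to cover 50% of its region.

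**Figure D2:**
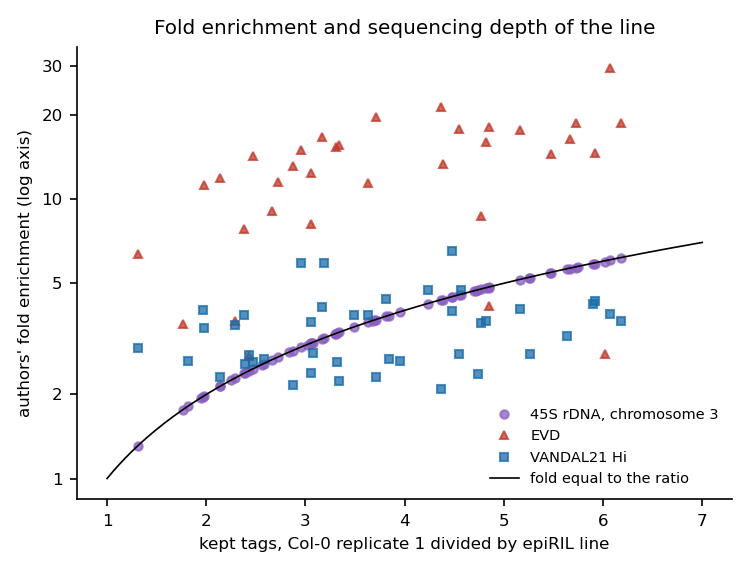
The authors' fold (vertical, log axis, no unit) at the 45S ribosomal DNA of chromosome 3, EVD and VANDAL21 Hi in each epiRIL with a call (points), against the kept tags of Col-0 replicate 1 divided by those of the line (horizontal, ratio). The curve marks a fold equal to the ratio; the ribosomal DNA lies on it (median fold over ratio 0.997), and it is no benchmark for EVD and VANDAL21 Hi, which do not reach the highest pileup.

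Away from these regions, the highest median folds among regions called in at least 4 lines and in neither Col-0 library were on transposons. EVD, an LTR retrotransposon of the ATCOPIA93 family (AT5G17125), was called in 34 of 67 lines (50.7%, Clopper-Pearson 95% interval 38.2 to 63.2) at chr5:5629887–5635422. Its median fold was 13.8, with quartiles of 8.78 and 16.6, and the highest fold of all 15949 peaks was 29.6 at EVD in epi61. ATR (AT1G34967), the other ATCOPIA93 copy, was called in 33 lines at chr1:12753459–12760514 with a median fold of 8.53. The Mutator-like element VANDAL21 Hi, whose genes are VANA, VANB and VANC, was called in 42 lines (62.7%, 50.01 to 74.2) at chr2:10001477–10009636, with a median fold of 3.5 and at most 6.53 in epi19. None of these elements was called in a Col-0 library, and with 2 such libraries the exact Fisher p was 0.493 for EVD and 0.150 for VANA. Intervals on shares of lines cover counting error only.

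Other elements were called in fewer lines. AT2G01029 (chr2:31764–36347) was called in 14 lines with a median fold of 4.11 and at most 11.1 in epi09. AT5G28120 (chr5:10106803–10114521) was called in 6 lines with a median fold of 4.21, and 15.4 in epi36. An unannotated stretch at chr4:2605947–2607180 was called in 5 lines, with a median of 3.64 and 7.51 in epi33. The LTR retrotransposon ATCOPIA13 (AT2G13940) was called in epi31 and epi52 with folds of 3.02 and 3.90, and ATCOPIA21 (AT5G44925) in epi18 and epi20 with 3.2 and 4.17. The Mutator element AtMu1 (AT4G08680) was called in epi01 and epi34 with folds of 2.13 and 2.40, and in epi34 it lies inside the 1170 kb stretch of chromosome 4 where that line had 186 regions of its own. Of the 8 copies of the heat-responsive retrotransposon ONSEN, AT1G48710 was called in epi12 with a fold of 1.5 and the others in no line. None of 9 genes of DNA methylation, MET1 and the chromatin remodeller DDM1 among them, was called in any line, and neither was any of the 3 single-copy genes ACT2, PP2AA3 and GAPC1. A count of 0 of 67 lines allows a share of up to 4.48%.

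**Figure D3:**
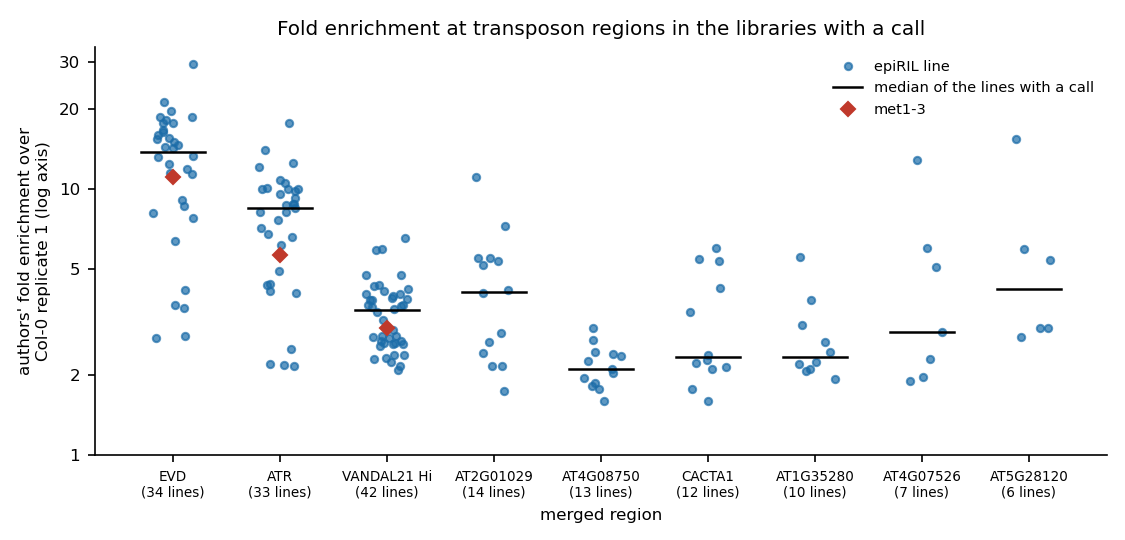
The authors' fold over Col-0 replicate 1 (vertical, log axis, no unit) at 9 transposon regions (horizontal), with 1 point per epiRIL that has a call, a bar for their median and a diamond for met1-3. EVD reaches 29.6 and CACTA1 6.01, and met1-3 has calls at EVD, ATR and VANDAL21 Hi only.

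CACTA1 (AT2G12210), an autonomous CACTA transposon, was called in 12 of 67 lines (17.9%, Clopper-Pearson 95% interval 9.61 to 29.2) at chr2:4900825–4909251, in neither Col-0 library and not in met1-3. The lines were epi03, epi06, epi07, epi09, epi10, epi12, epi13, epi14, epi26, epi38, epi48 and epi58. Its median fold was 2.33, with quartiles of 2.14 and 4.52, from 1.59 to 6.01 in epi07. CACTA1 was the only region over a model that the annotation or the fixed lists name as CACTA, 1 of 583 (0.172%) against 0.0475% in random placements on the same chromosomes (permutation p = 0.247, adjusted 0.424). Copia elements lay under 5 regions (0.858% against 0.0602%, permutation p = 0.001, adjusted 0.00599) and Mutator elements under 3 (0.515% against 0.0451%, permutation p = 0.002, adjusted 0.00599). The Mutator share lost its call where elements had to cover 50% of a region (0.172%, permutation p = 0.0879) and with gaps of 1000 bp bridged (0.749%, permutation p = 0.0220 before adjustment, no longer under 0.05 after it). A hAT element lay under 1 region, and no Gypsy or LINE model under any. The shares of named classes rest on the elements listed in advance, which make up 12 of the 18 Copia, 4 of the 16 Mutator and 1 of the 11 CACTA models. Without those elements, an alternative chosen after seeing the data, no region lay over a Copia, Mutator or CACTA model (0.0201, 0.0264 and 0.0437% in placements, permutation p = 1 for each), and models outside the list are too few to test a class as a whole.

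By line, CACTA1 alone made up the CACTA class with its 12 lines, Copia elements were called in 36 lines (53.7%, 41.1 to 66) and Mutator elements in 43 (64.2%, 51.5 to 75.5). The exact Fisher p against 2 Col-0 libraries without a call was 1, 0.225 and 0.139 (adjusted 1, 0.675 and 0.675). At least 1 transposable element of any class was called in all 67 lines (exact Fisher p = 4.26e-04, or 0.0147 against Col-0 replicate 2 alone); over AT4G06477, every line had a peak. Across the 67 lines, the CACTA1 call did not follow the number of other transposon regions (Pearson r = -0.0426, permutation p = 0.827; Spearman rho = 0.00102, permutation p = 0.996; r = -0.0339 without 2 lines). With a single CACTA region, the 2 lines left out were merely the first of the 12 tied lines with a call. Their removal is thus no check for outliers. Without epi34, r was 0.0901. With classes assigned by sequence similarity to the named elements, an alternative chosen after seeing the data, 12 regions were CACTA-like (2.06% against 0.917%, permutation p = 0.00799) and 66 lines had a peak over a CACTA-like model (exact Fisher p = 0.00128, adjusted 0.00192). All 66 had one over the edge of AT4G06700, and 17 had one over any other such model. Copia-like elements were then called in all 67 lines (exact Fisher p = 4.26e-04). Both of these Fisher tests by line count Col-0 replicate 1, whose lack of peaks was fixed, as a Col-0 library. Which Copia-like models made up their count is not given here. Depth differed between the lines and Col-0, so these counts do not show extra copies of such elements in these lines. The correlation across lines was then r = 0.734 (permutation p = 0.00663; rho = 0.0298, permutation p = 0.811; r = 0.0673 without 2 lines), and it rested on epi34. Without epi34 the CACTA-like share was 1.26% (permutation p = 0.377), the Mutator-like share 1.51% (permutation p = 0.651), the Copia-like share 3.02% (permutation p = 0.0609) and r = 0.0114.

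Transposable elements of any class lay under 177 of the 583 regions (30.4%) against 13.2% in random placements (permutation p = 0.001, the smallest possible). Most of these regions came from epi34: without it the share was 13.9% against 11.6% (permutation p = 0.197). Per library, 10.7 ± 3.59% of the peaks of a line lay over such elements (SD, n = 67) and 0 of the 42 peaks of Col-0 replicate 2, which allows up to 7.14% (exact permutation p = 0.0294). That test has a single control library, so its p says only that this library was extreme among the lines. The regions gathered around the centromeres: 409 of 563 nuclear regions (72.6%) lay in the pericentromeric windows against 28.6% in placements (permutation p = 0.001). Without epi34 the share was 59.2% against 28.01%. Both placement tests move each region on its own, while many regions are neighbouring pieces, such as those private to epi34. Their p-values may thus overstate the certainty.

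Line epi34 carried 186 regions called in no other library, all between chr4:4873864 and 6043821, and epi69 carried 58, of which 57 lay between chr3:21461069 and 21639993. These stretches were singled out after their values were seen. The stretch of epi34 spans 1170 kb in the pericentromere of chromosome 4, 64.7% of it under its private regions, with a median fold of 1.93. It covered 99 protein-coding genes, among them the homeobox gene KNAT1 (AT4G08150), and 85 transposable element genes. The stretch of epi69 spans 179 kb of the arm of chromosome 3, 91.9% of it called, with a median fold of 2.17. All 71 gene models in it were called, 57 of them protein-coding, including the LOB-domain gene LBD29 (AT3G58190), the zinc finger gene GIS (AT3G58070) and the RING finger gene SINAT2 (AT3G58040), and none was a transposable element. Line epi12 carried 47 such regions, and 16 of them lay in one window of 2 Mb, between chr3:13687009 and 14218626, against at most 8 in placements. They covered 1.53% of that span and none of its gene models, so they form no unbroken stretch. In all, 404 of the 583 regions were called in 1 line only.

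**Figure D4:**
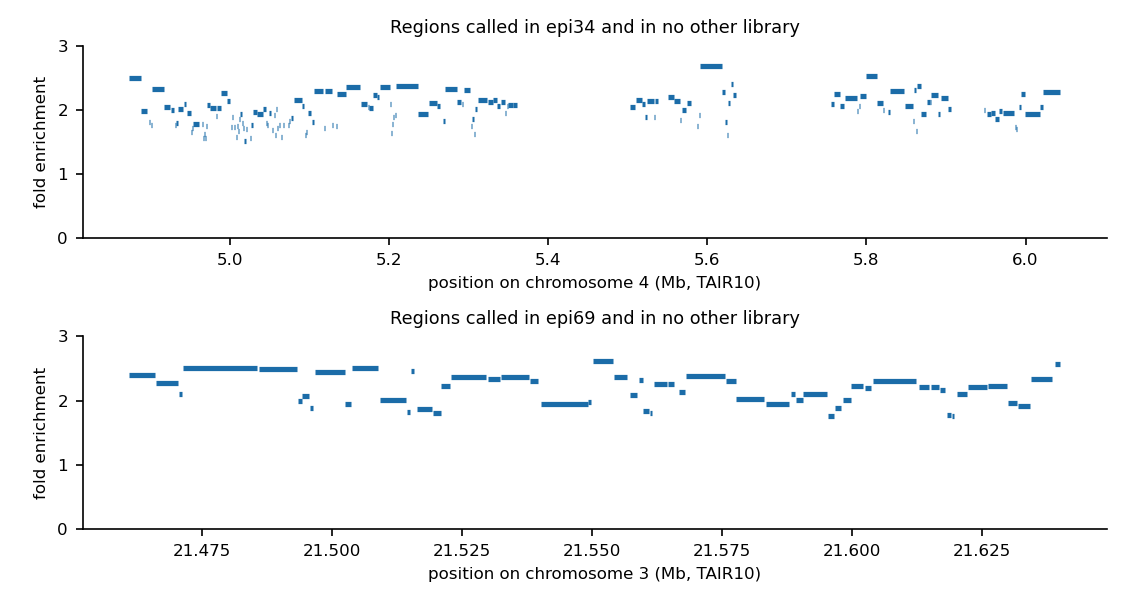
Regions called in epi34 and in no other library on chromosome 4 (upper panel) and in epi69 on chromosome 3 (lower panel), each drawn as a bar from its start to its end (horizontal, Mb on TAIR10) at the authors' fold of the region (vertical, no unit). The bars lie between 1.41 and 2.67 in epi34 and between 1.76 and 2.62 in epi69.

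The met1-3 library had calls on EVD (fold 11.1), ATR (5.66) and VANDAL21 Hi (3.00), and none on CACTA1, AT2G01029 or AT5G28120. These folds were not tested against those of the lines, which were sequenced deeper. The label does not say that this sample was the parent plant of the lines. Whether a fold as low as that of CACTA1 could be called at its depth was not tested. The lack of a call there thus does not show that the CACTA1 calls are new in the lines. The peaks of met1-3 covered 802.2 kb against a mean of 802.6 kb in the lines, so it had no excess of covered length. Its 280 peaks exceeded the mean of the epiRILs by 46.8, within the spread of the lines (exact permutation test, p = 0.588; 1 library against 67 can give 0.0147 at the smallest). Counting only peaks with a fold of at least 2 the excess was 115 (exact permutation p = 0.0147). This test rests on the shallowest library of all, whose fold at the ribosomal DNA of chromosome 3 was 8.81 against at most 6.14 in the lines. Outside the organelle chromosomes, ribosomal DNA and the insertion the count was below the lines' mean, by a difference of -12.8 (exact permutation p = 0.279). Of the 583 regions, 84 were also called in met1-3, and these were called in 62.0 lines on average against 2.83 for the others. The difference of 59.1 lines had a permutation p of 0.0001, the smallest possible, across regions, which are not independent replicates. All lists share Col-0 replicate 1 as control, which by itself gives shared calls, so this p does not test descent from met1-3.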

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

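The tests on the recurrent regions in this part were chosen only after the result was seen. The pileup column entered none of the comparisons: 192 peaks of the epiRILs stood at the highest possible pileup of 800, with at least 1 in each of the 67 lists, against 0 in both Col-0 lists, whose highest was 727, and 0 in met1-3, whose highest was 799. The lists hold called peaks only and the Col-0 lists have no call at these regions, so the count does not show a higher pileup in the lines than in Col-0. They lay at the 45S ribosomal DNA of chromosome 3 (66 lists), the plastid chromosome (66), the ribosomal DNA of chromosome 2 (42), chr3:13588578–13592903 (17) and the region at the edge of AT4G06700 (1).

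These 5 are among 66 regions called in 60 or more lines and not in Col-0 replicate 2. At the 5, the authors' fold divided by the ratio of kept tags, control over line, had a median of 0.997 (0.968 to 0.998), consistent with a control in which 1 tag per position had filled every position, so that the fold returns the scaling. At the other 61 the fold rose with that ratio across lines, with a median Spearman rho of 0.874 (0.420 to 0.999), which is consistent with the depth of the line as a source of these folds. The rho was lower, at a median of 0.606, for the 22 mitochondrial regions and those of the insertion than for the remaining nuclear ones (0.961), so organelle content stays open there. The epiRIL genotype stays open as an untested explanation, since both Col-0 libraries were deeper than every line.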

How the results depend on the processing

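Choices and alternatives were fixed before the data were examined, except the classes by sequence similarity or without the listed elements, the runs without epi34, epi12 or epi69, the nuclear counts without Col-0 replicate 1 and the classes by line without it, which were chosen only after the results were seen. Of 124 alternatives to results that answer a comparison, 104 kept direction and side of the threshold, 9 became weaker, 4 passed a threshold the main result had not, and 7 changed direction. Some of the 104 could not differ. Classes by similarity leave the results for any element unchanged, and the share of peaks over elements never included Col-0 replicate 1. Peak counts and covered length without replicate 2 were set against a fixed 0. The tally is thus no measure of robustness. Of the 9, the counts of 35, 31 and 32 regions fell but still hold regions that pass, and the other 6 no longer passed. The excess of peaks ranged up to 233 (without Col-0 replicate 2) and was 33.8 without organelle and ribosomal DNA, the insertion and Col-0 replicate 1, where it no longer passed, as the fixed 0 of that library was gone. The regions called more often in epiRILs were 58 and became 0 at a fold of at least 2, 35 without organelle and ribosomal DNA and the insertion, 31 with gaps of 1000 bp bridged, 32 with 50% cover and 0 to 63 when a library was left out. With a single Col-0 library, a region in every line can reach no less than 0.0147 before adjustment, which is why that count ended at 0. For the other changes the cause was not tested. The excess of met1-3 over the epiRILs passed at a fold of at least 2 (115 peaks) and was -12.8, exact permutation p = 0.279, without organelle and ribosomal DNA and the insertion. The share of regions over any element was 13.9 to 33.7% when epi34, epi12 or epi69 was left out, the call ending without epi34, which removes 186 of 583 regions; it was 13.9% too with classes by similarity and without epi34. Similarity classes took the CACTA share to 2.06% and the lines with a CACTA-like call to 66 (65 without epi34), and turned the correlation from -0.0426 to 0.734; more models count as CACTA there. Without the listed elements the CACTA, Mutator and Copia shares were 0%, under those of placements, as no other model of these classes was called. The correlation was also positive, without a call, at a fold of at least 2 (0.0110), with gaps bridged (0.0238), without epi34 (0.0901, against -0.0554 without epi12) and with similarity classes without epi34 (0.0114). The share of peaks over elements had no value without Col-0 replicate 2 or at a fold of at least 2, as no Col-0 peak remained. Among the lines, kept tags were unrelated to the number of peaks (r = 0.0968, permutation p = 0.437; rho = 0.0205) but ranked with nuclear peaks outside the windows (rho = 0.363, permutation p = 0.00275, adjusted 0.0110; r = 0.250, permutation p = 0.0362, adjusted 0.145; 4 relations). Depth and group cannot be told apart, as both Col-0 libraries were deeper than every line, and with 2 Col-0 libraries no region called in fewer than 64 lines passed.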

Other observations

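In this part the share of private regions over elements in epi34, the other copies of private regions in the reference and the sequence shared by CACTA1 and the AT4G07526 element were tested as planned before their results were seen, and all other tests were chosen only after the result was seen. Of 598 nuclear regions, 3 had a terminal motif of CACTA elements within 150 bp of both edges. Without CACTA1 itself 2 of 597 did, against a mean of 0.023 and at most 1 in 1000 random placements (permutation p = 0.001, the smallest possible), and without AT1G35280 too, which shares its sequence, 1 of 596 did (permutation p = 0.024). The 3 were CACTA1 (ends at chr2:4900803 and 4909281), AT1G35280 (chr1:12942847 and 12947011), and AT4G07526 (chr4:4358131 and 4360293). AT1G35280, a transposable element gene, was called in 10 lines (14.9%, Clopper-Pearson 95% interval 7.40 to 25.7) with a median fold of 2.33 and 5.56 in epi07. AT4G07526 codes for an uncharacterized protein and lies inside its element; it was called in 7 lines, epi01, epi24, epi26, epi36, epi46, epi60 and epi68 (10.4%, 4.31 to 20.4), with a median fold of 2.91 and 12.9 in epi26. Neither was called in Col-0 or met1-3.

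Gene regions and single elements outside the naming rule were also called. Regions named by the transcribed pseudogenes AT2G07600 (chr2:3188070–3189537) and AT3G33004 (chr3:13540376–13541185) were called in 47 and 45 lines. Their sequence was like that of an organelle over 100 and 99.8% of the region. The region named by AT2G07776, in the insertion, was called in 54. The region named by the ubiquitin gene UBQ13 (AT1G65350, chr1:24273015–24275794) was called in 50 lines with a median fold of 1.77 and in neither Col-0 library. The called region, not the gene as a whole, was measured as wholly like the sequence of an organelle. The region of the element AT4G08750 (chr4:5579652–5586469) was called in 13 lines with a median fold of 2.11; 1 of them is epi34 (fold 1.82), whose stretch on chromosome 4 includes it.

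Transposon regions were called together in some pairs, of 9 tested, and not in others. EVD and CACTA1 shared 3 lines against 6.09 by chance (exact Fisher p = 0.0615, adjusted 0.185). VANDAL21 Hi shared 23 lines with EVD against 21.3 (exact Fisher p = 0.454) and 9 with CACTA1 against 7.52 (exact Fisher p = 0.512). AT1G35280 and AT4G07526 shared 2 against 1.04 (exact Fisher p = 0.279). All 33 lines with ATR also had EVD (exact Fisher p = 2.46e-18, adjusted 2.21e-17), 100% of them, and EVD and ATR are 99.5% identical over 4227 bp, so reads shared between EVD and ATR may carry the pair. CACTA1 and AT1G35280 shared 6 lines against 1.79 by chance (exact Fisher p = 0.00136, adjusted 0.00611), and alignments of 90% identity or more cover 98.4% of AT1G35280, with 98.6% identity in the longest, so shared reads may add here too; AT2G01029 covers 99.7% of AT5G28120 and 71.9% of AT4G08750 in the same way (94.1 and 95.9% identity), yet they shared 2 lines against 1.25 (exact Fisher p = 0.597) and 3 against 2.72 (exact Fisher p = 1), on 6 and 13 lines, whose intervals of 4.33 to 77.7% and 5.04 to 53.8% leave this open. Reads shared between CACTA1 and the AT4G07526 element are argued against, since such alignments cover 0% of the element. Whether the AT4G07526 element gains reads in the lines where CACTA1 does cannot be told apart from chance, as only epi26 of its 7 lines has both (14.29%, 0.361 to 57.9; exact Fisher p = 1), and 7 lines are too few; no biological explanation was tested.

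The private regions of epi34 and epi69 lay in the stretches of chromosomes 4 and 3 that the report describes. An uneven library is argued against, as the lines had ordinary numbers of nuclear peaks outside their own stretch and the windows: epi34 had 63 and epi69 had 61, and at most 19.7% of the 66 other lines had fewer. Reads shared among repeat copies may add to the stretch of epi34. There 65.6% of the private regions lay over transposable elements against 41.6% in placements inside it (permutation p = 0.001). Of all its private regions, 54.3% (Clopper-Pearson 95% interval 46.9 to 61.6) had another copy in the reference over at least 50% of their bases (39.2% of all bases). As the whole cause, shared reads are argued against only by a test chosen after the result was seen. In it 15.1% (10.2 to 21.02) had no other copy at all, at a median fold of 1.85 against 1.94 for the rest. In epi69 shared reads are argued against, since 1.72% of its 58 private regions (0.0436 to 9.24) had another copy over at least 50% of their bases. No biological explanation was tested, as the design names none for single lines.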
